A study of Mus musculus with 14 samples.

How the data were processed

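Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open chromatin, in 14 libraries of sgRNA-transduced mouse OT-I CD8 T cells taken from mice bearing the ovalbumin-expressing melanoma B16-Ova. Per the labels, 4 libraries were wild type (WT), 4 lacked Regnase-1 (Reg1_KO), 2 lacked Batf (Batf_KO) and 4 lacked both (BatfReg1_dKO, called dKO below). The labels do not say whether the libraries came from separate animals, so every p-value measures the spread between these libraries and nothing wider. All library descriptions carry the same lane label, and the labels give no batch.

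The deposited table holds 125287 non-overlapping regions, each with 1 value per library, and the unit is called signal here. To make this signal the authors multiplied the whole counts of read ends in each library, called reads below, by 1 constant. These are not counts of fragments. Every value is a whole multiple of the smallest value of its library (tolerance 0.01), which allowed the reads to be recovered. The constants times the median-of-ratios size factors recomputed from the recovered reads lay between 0.999 and 1.00, so the deposited values behave as counts divided by such size factors. What the constants were computed from is not given in the sources used here. No value is 0, and the lowest read count in every library is 1, so that counts of 0 appear to have been raised to 1 read or the regions to have been chosen to have none. The processing notes name Trimmomatic 0.36, Picard 2.9.4, SAMtools, MACS2 2.1.1 and bedtools, without role or order, and the builds mm9 and NCBIM37; the aligner is not given in the sources used here. The coordinates are those of mm9 as the table gives them. Region annotation, distance to the nearest transcription start site (TSS) and gene names come from the deposited table.

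Recovered reads over the regions ran from 9054716 to 17231196 per library. With 1.5-fold, 2-fold and 4-fold changes put into simulated data of the same depth and spread, the test for Reg1_KO against WT recovered 17.9%, 55.2% and 98.5% of changed regions, and 67.2%, 88.1% and 93.9% of changed genes. For the interaction the shares were 0%, 26.9% and 80.3% of regions and 43.3%, 70.1% and 84.8% of genes. At most 11 unchanged regions or genes were called in any comparison. Only 67, 67 and 66 regions, all above the median signal, or as many genes, were changed, in the order of the folds. With so few changes the adjusted threshold is stricter than in the real comparisons, so these shares do not give the power there.

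Regions with a signal of at least 10 in at least 2 libraries were tested, which kept 124698 and left out 589. The test chosen before the data were examined was edgeR for counts and limma for normalized values. Since the values are normalized, limma 3.58.1 (R 4.3.3) was used on log2(signal + 1), with a mean-variance trend and 1 coefficient per group in a single fit of the 14 libraries. The 2 Batf_KO libraries therefore share the estimate of spread of the other groups. Comparisons were Reg1_KO, Batf_KO and dKO with WT, dKO with Reg1_KO and with Batf_KO, and the interaction, which is (dKO minus Reg1_KO) minus (Batf_KO minus WT). Tests were two-sided, adjusted p-values are Benjamini-Hochberg values within each comparison, and calls were made at 0.05. Errors of log2 changes are standard errors from limma, and errors of group means are SD over libraries.

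For gene-level values the deposited signal of all tested regions given the same gene name was summed, without a limit on distance, which gave 19568 genes. A region's gene is the one whose TSS is nearest in the deposited annotation, which is no evidence that the region regulates it. Promoter regions were those within 1 kb of a TSS, with 2.5 kb as an alternative, and shares were compared by Fisher's exact test.

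Written before the data were examined were 17 gene lists: memory and stemness, effector, exhaustion, AP-1 and IRF factors, cytokine and STAT5 genes, TCR signalling, Regnase-1 mRNA targets, mitochondrial respiration, glycolysis, cell cycle, tissue residency, and markers of B cells, myeloid cells, melanoma, NK cells, CD4 and regulatory T cells, and stroma. They hold 284 symbols, of which 266 were measured. Each list was tested with camera (limma, inter-gene correlation 0.01), adjusted over the 17 lists within a comparison, and again with an estimated correlation. Camera compares a list with all other genes, so a list can be called against a shifted background. Beside it stands the number of members called over all genes and the number called when p-values were adjusted over the list alone.

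Genes named in the text follow a rule set at the same time. Part (a) took, per comparison, the 6 largest rises and 6 largest falls among called regions of at least median signal whose libraries did not overlap between the groups (no such condition for the interaction), 1 region per gene and without clone names. Part (b) took, for each list, the called gene with the lowest adjusted p in each direction. Part (c) always took certain genes, among them Batf, Zc3h12a, Tcf7, Ifng, Gzmb, Pdcd1 and Tox, with the region of each that had the lowest p. Further list members given as examples were chosen after their values were seen. A few genes that met the rule are not reported here, and no others took their places.

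Alternatives fixed before the data were examined were total-count scaling, loess offsets (span 0.3), no filter, only regions at or above the median signal, a replicate block, each library left out in turn, only the groups compared, gene values from promoter regions alone, an adjusted p of 0.01 and DESeq2 1.42.0 on the recovered reads. Chosen after seeing the data were edgeR 4.0.16 on the recovered reads, TMM scaling, scaling to equal medians over promoter regions, pseudocounts of 0.5 and 5, gene values from regions within 100 kb or beyond 1 kb of a TSS, leaving out regions with a value of 1 read, and leaving out the 3 libraries nearest to another group. A search for sequence motifs had been planned but was not run, because no mm9 sequence was at hand, and GC content was not tested for the same reason. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.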

Results

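Accessible chromatin was measured by ATAC-seq in OT-I cells, CD8 T cells whose receptor recognises an ovalbumin peptide, recovered from mice bearing the ovalbumin-expressing melanoma B16-Ova. The cells had been transduced with sgRNAs, and the labels give 4 genotypes: wild type (WT, 4 libraries), without Regnase-1 (Reg1_KO, 4), without Batf (Batf_KO, 2) and without both (BatfReg1_dKO, here dKO, 4). Regnase-1, encoded by Zc3h12a, is an RNase that degrades mRNAs of activated immune cells, and Batf is an AP-1 family transcription factor active in effector T cells. Reads over the 125287 regions numbered 15318897 to 17231196 per library in WT, 9054716 to 11474599 in Reg1_KO, 10737378 to 12259177 in Batf_KO and 10208415 to 11316217 in dKO. The median region was 500 bp wide. By the deposited annotation, 45.7% of regions lay in introns, 36.7% between genes and 10.98% at a promoter. Values below are deposited signal (normalised read counts), changes are log2 changes ± SE from limma, and group means are ± SD, with n = 4 except for Batf_KO (n = 2).

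The 4 genotypes separated from one another. Spearman correlations across regions were 0.916 to 0.942 for the 19 pairs of libraries within a genotype and 0.778 to 0.899 for the 72 pairs between genotypes; regions are not independent replicates. On the first principal component, which held 32.1% of the variance, Batf_KO and WT lay at one end, Reg1_KO at the other and dKO in between. The second, with 19.6%, set dKO apart.

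**Figure D1:**
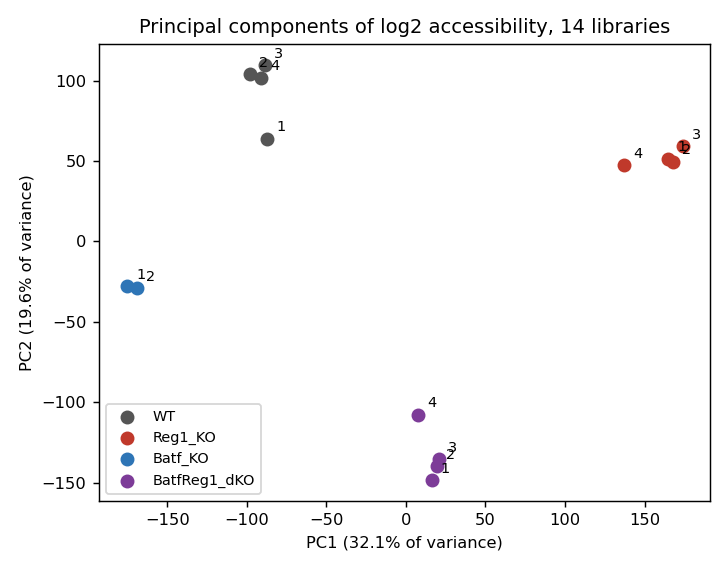
Each point is 1 of the 14 libraries, placed by its first principal component (x axis, 32.1% of variance) and second principal component (y axis, 19.6%) of log2 signal over the tested regions, with colours for the 4 genotypes. The genotypes form separate groups.

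Promoter regions took up different shares of the signal. Regions within 1 kb of a transcription start site (TSS) held 50.9% ± 1.35 of the signal in WT, 40.4% ± 1.08 in Reg1_KO, 53.3% ± 0.835 in Batf_KO and 46.2% ± 1.21 in dKO. Every Reg1_KO library (38.8% to 41.1%) lay below every dKO library (45.2% to 48.0%), and these lay below every WT library (49.1% to 52.3%). Because this share moves with genotype, gene sums and counts of rises and falls depend on how libraries are scaled, and these dependences are given with each comparison.

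**Figure D2:**
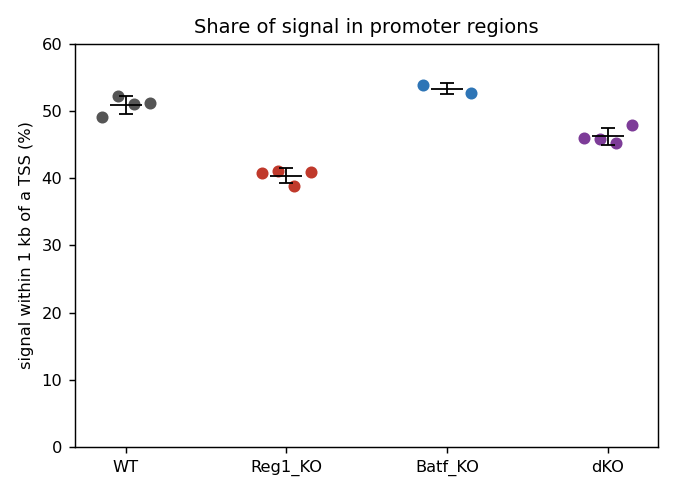
Points give the percent of each library's signal that lies within 1 kb of a TSS (y axis), by genotype (x axis), with bars for the mean and error bars for the SD. Means run from 40.4% in Reg1_KO to 53.3% in Batf_KO.

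Zc3h12a and Batf, the targeted genes, are edited by sgRNAs in ways that accessibility cannot check. Summed signal at Zc3h12a was 2617 ± 112 in WT, 2547 ± 73.1 in Reg1_KO, 2973 ± 27.9 in Batf_KO and 2686 ± 133 in dKO. At Batf it was 2049 ± 94.9, 2700.1 ± 67.3, 2264 ± 285 and 3475 ± 154 in the same order.

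**Figure D3:**
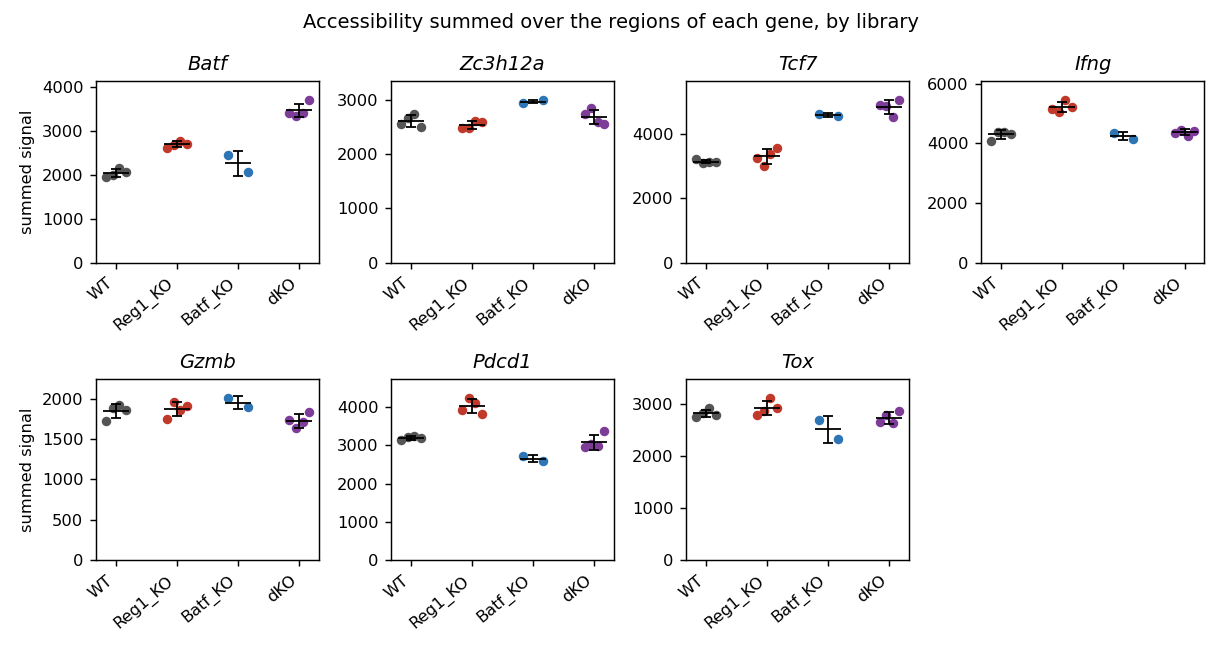
Panels show the summed signal (y axis, normalised read counts) over all tested regions given to Batf, Zc3h12a, Tcf7, Ifng, Gzmb, Pdcd1 and Tox, by genotype (x axis). Points are libraries, and bars are means with SD. Tcf7 ran from 3140.1 ± 55.1 in WT to 4841 ± 221 in dKO, and Pdcd1 was highest in Reg1_KO at 4015 ± 181.

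Reg1_KO against WT asks what loss of Regnase-1 changes (4 libraries each). Accessibility rose most, among genes of the lists, at Kit, a receptor tyrosine kinase, from 567 ± 27.3 to 2026 ± 192 (log2 change 1.83 ± 0.07, limma adjusted p 1.03e-24). It also rose at the cytokine gene Il6 (1.69 ± 0.08), at Cd40lg, a helper-type TNF family ligand (245 ± 33.2 to 689.9 ± 36.6), and at Itga1, a collagen-binding integrin of resident T cells (1.20 ± 0.06). Further rises were at the costimulatory receptor Icos (1413 ± 60.6 to 3049 ± 181, 1.11 ± 0.05) and at the transcription factor Maf (4485 ± 88.1 to 9487 ± 412, 1.08 ± 0.04). It fell at the mitotic kinase Aurkb (1589 ± 190.0 to 610.3 ± 69, -1.38 ± 0.07), at the lactate transporter Slc16a3 (-1.10 ± 0.07) and at the AP-1 gene Jund (-1.06 ± 0.06). Pdcd1, which encodes the inhibitory receptor PD-1, rose by 0.33 ± 0.05 (adjusted p 2.74e-08). Batf (0.40 ± 0.05) and the cytokine Ifng (0.28 ± 0.04) rose too, but the sign of both turned when promoter regions alone were summed, to -0.16 and -0.30. Over promoter regions alone Icos did not pass (0.15). Tcf7, a factor of memory and stem-like T cells, did not pass the test (0.07 ± 0.04), nor did Gzmb (0.02 ± 0.05), Tox (0.05 ± 0.05) or Zc3h12a (-0.04 ± 0.05). Over promoter regions alone Tcf7 (-0.31), Gzmb (-0.63) and Tox (-0.74) passed as falls, and Zc3h12a passed as a rise with edgeR (0.19) and with equal promoter medians (0.29).

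Of 124698 tested regions, 23413 rose and 22414 fell in Reg1_KO, of which 11404 and 7204 changed at least 2-fold. The largest rise under the naming rule lay in an intron at chromosome 1, 152236813 to 152237312, assigned to Tpr, from 7.9 ± 2.95 to 238 ± 30.5 (4.79 ± 0.20, adjusted p 2.09e-26). Other large rises lay in regions assigned to Erich3 (between genes, chromosome 3, 154346552 to 154347051, 4.75 ± 0.28), Zfp704 (4.55), Frmpd4 (4.47) and Schip1 (4.37). The largest fall under that rule lay between genes upstream of Fry (chromosome 5, 151026038 to 151026537), from 282 ± 26 to 24.8 ± 11.3 (-3.56 ± 0.19, adjusted p 8.97e-23), followed by Os9 (-3.19), Sar1a (-3.00), Rbl2 (-3.00), Homez (-2.85) and Rap1gap (-2.85). Single regions of the immune genes, each with the lowest p of its gene, moved further than their sums, which that choice favours. An intron region of Batf (chromosome 12, 87034116 to 87034615) rose from 8.99 ± 3.12 to 77.1 ± 10.6 (3.03 ± 0.27), and a region upstream of Tcf7 (chromosome 11, 52133920 to 52134419) from 21.3 ± 6.45 to 121 ± 23.6 (2.47 ± 0.20). A region downstream of Ifng (chromosome 10, 117932338 to 117932837) rose by 1.69 ± 0.12. In Pdcd1 and Tox, intron regions rose by 1.28 ± 0.12 and 1.33 ± 0.15. The Gzmb promoter fell (-0.64 ± 0.10), as did a Zc3h12a region near its TSS (-0.57 ± 0.08).

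Of the 17 gene lists 6 were called. Cell cycle genes fell at 17 of 22 measured and rose at 0 (median -0.33, camera adjusted p 0.00749), with Aurkb, Birc5 (-1.28) and Top2a (-1.21) furthest. Glycolysis genes fell at 15 of 19 and rose at 1, the glucose transporter Slc2a3 (0.30 ± 0.06, not past the test over promoter regions at 0.10), with Slc16a3, Pgam1 (-0.81) and Aldoa (-0.80) furthest (median -0.40, camera adjusted p 0.0215). Regnase-1 mRNA targets rose at 6 of 14 and fell at 2 (camera adjusted p 0.0215): Il6, Icos, Ptgs2 (0.83), Il4 (0.63), Cxcl2 (0.54) and Nfkbiz rose, and Nfkbid (-0.81, turning to 0.23 beyond 1 kb of a TSS) and Rel fell. Tissue residency genes rose at 6 of 13 and fell at 2 (camera adjusted p 0.0215), Itga1, Rgs1 (0.43) and the integrin Itgae (0.38) against Hic1 (-0.49 ± 0.06). CD4 and regulatory T cell markers rose at 4 and fell at 2 of 12 (camera adjusted p 0.0226): Cd40lg, Ikzf2 (0.53 ± 0.04, turning to -0.05 over promoter regions), Ccr4 and Gata3 rose, and Foxp3 (-1.21) and the CD4 lineage factor Zbtb7b (-0.31, turning to 0.01 with equal promoter medians) fell. Melanoma markers rose at 2 of 8 (camera adjusted p 0.0312), Kit and Trpm1 (0.42), while the pigment cell genes Mlana (-0.16), Pmel (0.04) and Dct (-0.10) did not pass. With an estimated correlation none of the 6 calls held, at camera adjusted p = 0.454, 0.47, 0.243, 0.272, 0.243 and 0.243 in the order above. None held from regions beyond 1 kb of a TSS (0.233, 0.802, 0.0891, 0.209, 0.233 and 0.677), and over promoter regions alone the Regnase-1 target, residency and CD4 lists were not called (0.0853, 0.0853 and 0.111). Counts adjusted over the list alone were the same.

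Among lists that were not called, exhaustion genes rose at 8 and fell at 7 of 19: the inhibitory receptors Pdcd1, Tigit (0.35) and Cd200r1 (0.49) rose, and Nr4a1 (-0.52 ± 0.05), a factor induced by receptor signals, and Lag3 (-0.61) fell. Memory and stemness genes rose at 8 and fell at 5 of 20, with Lef1 (0.55 ± 0.04) and the egress receptor S1pr1 (0.57) against Id3 (-0.67 ± 0.05) and Bcl6 (-0.40). Their list had a camera adjusted p of 0.0818 and was called upward with total counts (0.0298). Effector genes rose at 5 and fell at 8 of 20, with the granzyme Gzmk (0.86 ± 0.09) against Tbx21 (-0.66) and Runx3 (-0.48 ± 0.05). AP-1 and IRF factors rose at 8 and fell at 8 of 20, TCR signalling genes at 5 and 6 of 20 (Plcg1 0.43, turning to -0.58 over promoter regions, against Cd8a -0.36, not past the test with equal promoter medians at -0.03), and cytokine and STAT5 genes at 2 and 10 of 20. Mitochondrial genes fell at 21 and rose at 5 of 29 (median -0.45, camera adjusted p 0.0688), led by Ndufs1 (-1.08) and Ndufv1 (-1.02). Markers of other cell types rose and fell at 3 and 1 of 11 for B cells (Ebf1 0.64), 3 and 4 of 13 for myeloid cells (Mpeg1 0.94, C1qa -1.45), 5 and 4 of 12 for NK cells, and 5 and 4 of 10 for stroma (Kdr 1.09). Ebf1 (0.03) and Kdr (0.54) did not pass over promoter regions alone, from which the B cell and NK cell lists were called upward (0.0166 and 0.0174). Upward there is relative to all genes, whose median over promoter regions was -0.44. Adjusted over the list alone, exhaustion gave 9 rises and B cell markers 2 rises and 0 falls, and the other counts of this paragraph were the same.

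Promoters and other regions moved apart in Reg1_KO: the median log2 change was -0.41 within 1 kb of a TSS and 0.09 elsewhere. Promoters made up 15.8% of tested regions but 5.18% of those that rose and 44.4% of those that fell (Fisher's exact test, odds ratios 0.244 and 7.55). At gene level 3807 genes rose and 8522 fell, with a median of -0.18 over all genes. Scaling to equal promoter medians moved that median to 0.14 and the region median to 0.32, and total counts moved them to -0.06 and 0.12. Rises were 51.1% of called regions and 30.9% of called genes as deposited, 77.9% and 63.7% with equal promoter medians, 62.0% and 43.0% with total counts, and 41.6% of genes with loess offsets. With edgeR and DESeq2 they were 54.9% and 51.3% of called genes (medians 0.05 and 0.02). With equal promoter medians, cell cycle genes rose at 5 and fell at 9 (median -0.01), glycolysis genes at 6 and 7 and mitochondrial genes at 11 and 13.

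**Figure D4:**
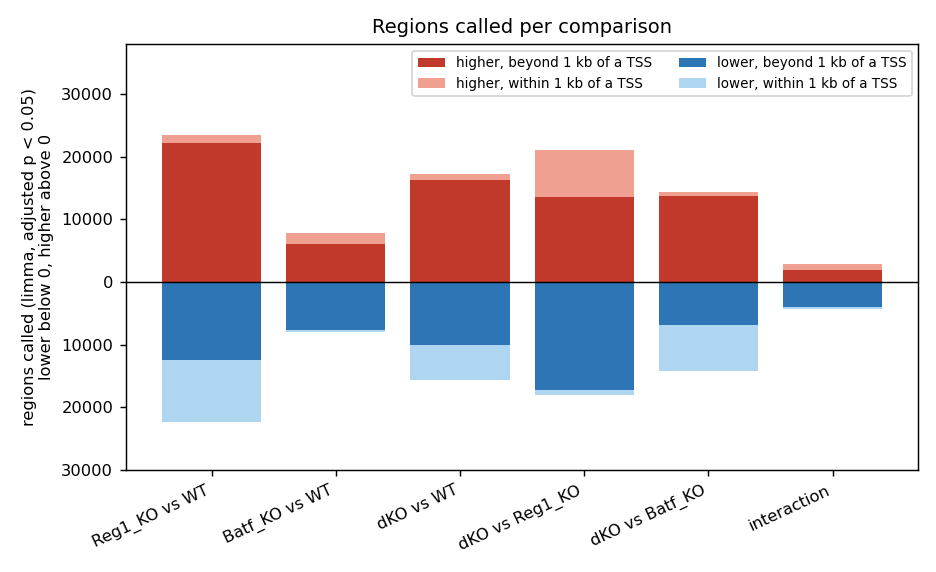
Bars give the number of regions called higher (above 0) and lower (below 0) in each of the 6 comparisons (x axis), split by whether the region lies within or beyond 1 kb of a TSS. In Reg1_KO against WT 23413 regions were higher and 22414 lower, and promoters made up 44.4% of the latter.

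Batf_KO against WT asks what loss of Batf changes (2 libraries against 4). Accessibility rose at Id3, an inhibitor of E proteins (1903 ± 74.7 to 3367 ± 185, 0.82 ± 0.07, limma adjusted p 2.71e-12), the lymph node homing receptor Ccr7 (0.73 ± 0.07) and Tcf7 (3140.1 ± 55.1 to 4589.8 ± 56.1, 0.55 ± 0.05, adjusted p 6.33e-10). It fell at the ectoenzyme Cd38 (972 ± 20.2 to 539 ± 24.8, -0.85 ± 0.08, adjusted p 2.32e-10), the inhibitory receptor Havcr2 (-0.57 ± 0.08), Gzmk (-0.84 ± 0.11), the repressor Prdm1 (4135 ± 275 to 3000.3 ± 190.4, -0.46 ± 0.06, adjusted p 9.67e-08) and Pdcd1 (3189 ± 46.4 to 2649.8 ± 82.6, -0.27 ± 0.06). Tox fell (-0.17 ± 0.06), with a value of 0.17 over promoter regions alone, and Zc3h12a rose by 0.18 ± 0.06. Zc3h12a did not pass with total counts (0.08) or without WT 4 (0.16), Batf_KO 1 (0.19) or Batf_KO 2 (0.18), and Tox did not without WT 2 (-0.17), WT 3 (-0.15), WT 4 (-0.18) or Batf_KO 2 (-0.07). Over promoter regions alone Cd38 (-0.33) and Prdm1 (-0.16) did not pass. Batf itself (0.14 ± 0.06), Ifng (-0.02 ± 0.05) and Gzmb (0.08 ± 0.07) did not pass the test.

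Memory and stemness genes rose at 12 of 20 and fell at 1, the chemokine receptor Cxcr3 (-0.42 ± 0.08). Adjusted over the list alone, 15 rose (median 0.23, camera adjusted p 2.33e-06, and adjusted p = 0.0557 with an estimated correlation). AP-1 and IRF factors rose at 11 of 20 and fell at none, with Nfatc2 (0.34 ± 0.05) and Irf4 (0.38), and at 16 adjusted over the list alone (camera adjusted p 4.43e-05, held at adjusted p = 0.0326 with an estimated correlation). NK cell markers fell at 4 and rose at 1 of 12 (6 and 1 adjusted over the list alone), namely the receptors Klra8 (-1.10 ± 0.16), Klra7 (-0.85) and Klra1 and the granzyme Gzma (-0.63) against Tyrobp, which did not pass with total counts (0.22; camera adjusted p 0.000366, held at adjusted p = 0.0325 with an estimated correlation). Activated CD8 T cells can express genes of this list too. Effector genes fell at 6 and rose at 2 of 20, Cx3cr1 (0.33 ± 0.07, not past the test over promoter regions at 0.19) and Tnf being the rises (camera adjusted p 0.00149, adjusted p = 0.557 with an estimated correlation; the same counts adjusted over the list alone). Exhaustion genes fell at 7 and rose at 3 of 19, Nr4a1 (0.51 ± 0.06), Lag3 and Nr4a3 being the rises, with 8 falls adjusted over the list alone (camera adjusted p 0.00149, lost at adjusted p = 0.412 with an estimated correlation and 0.236 over promoter regions). Cytokine and STAT5 genes rose at 11 and fell at 1 of 20, with the cyclin Ccnd2 (0.64 ± 0.08), Socs3 (0.52) and the IL-2 receptor chain Il2ra (0.39 ± 0.07, not past the test over promoter regions at 0.19) against the cytokine Il21 (-0.74 ± 0.11), and 13 and 3 adjusted over the list alone. That call (camera adjusted p 0.0361) was lost with an estimated correlation (adjusted p = 0.557) and with total counts (0.114), and its direction turned over promoter regions alone (0.703). Other markers of cell types, not called, rose and fell at 2 and 1 of 11 for B cells, 2 and 2 of 12 for CD4 and regulatory T cells, 2 and 1 of 13 for myeloid cells, 1 and 0 of 10 for stroma and 0 and 0 of 8 for melanoma.

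At region level 7866 regions rose and 7961 fell, 2953 and 4707 of them at least 2-fold. Under the naming rule the largest rises were assigned to Arl4d (chromosome 11, 101558475 to 101558974, 2.75 ± 0.28), Foxp1, a factor of quiescent T cells (an intron, chromosome 6, 99140776 to 99141563, 11.2 ± 4.02 to 75 ± 1.38, 2.69 ± 0.29), Gng10 (2.68), Orm1 (2.57), Dock4 (2.42) and Foxr1 (2.41). The largest falls under that rule were assigned to Slmap (chromosome 14, 27300867 to 27301366, -3.46 ± 0.33), Khdc1b (-3.15), Jak2, a cytokine receptor kinase (an intron, chromosome 19, 29330908 to 29331407, 147 ± 11.1 to 16.6 ± 5.03, -3.09 ± 0.25, adjusted p 7.76e-14), Mtss1 (-3.03), Ubxn2b (-2.98) and Phtf2 (-2.95). A promoter region of Tcf7 (chromosome 11, 52096602 to 52098206) rose by 1.25 ± 0.19, and an intron region of Pdcd1 (chromosome 1, 95938757 to 95939256) fell from 439 ± 47.7 to 234 ± 0.892 (-0.90 ± 0.14). Promoters had a median change of 0.14 against -0.03 elsewhere, and made up 22.4% of rises and 3.49% of falls (Fisher's exact test, odds ratios 1.59 and 0.181).

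At gene level 2763 genes rose and 1133 fell. Rises were 49.7% of called regions and 70.9% of called genes as deposited, 33.8% and 37.8% with total counts, 32.7% and 35.5% with equal promoter medians, 56.2% of genes with loess offsets and 50.8% and 49.1% of genes with edgeR and DESeq2, as the gene median moved from 0.09 to -0.02 under the first 2 of these. Memory genes rose at 6 of 20 and AP-1 and IRF factors at 3 of 20 with equal promoter medians. With only 2 Batf_KO libraries, leaving 1 out moved counts: rising regions to 3270 without Batf_KO 1 and 3926 without Batf_KO 2, and falling regions to 5257 without Batf_KO 2. It moved rising genes to 842 and 1761 and falling genes to 652 and 703 without Batf_KO 1 and 2, the remaining library being assumed to vary like the other groups.

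dKO against WT asks what loss of both genes changes (4 libraries each). Accessibility rose at Cd40lg (245 ± 33.2 to 736 ± 44.9, 1.59 ± 0.09, limma adjusted p 1.81e-18), Kit (567 ± 27.3 to 1706 ± 54.5, 1.59 ± 0.07), Icos (1413 ± 60.6 to 2723 ± 121, 0.95 ± 0.05), Batf (2049 ± 94.9 to 3475 ± 154, 0.76 ± 0.05, adjusted p 4.75e-16), Maf (0.63 ± 0.04) and Tcf7 (3140.1 ± 55.1 to 4841 ± 221, 0.62 ± 0.04, adjusted p 4.6e-15). It fell at Rgs16, a regulator of G protein signalling (1147 ± 130.2 to 693 ± 75.6, -0.73 ± 0.08), at the costimulatory receptor Tnfrsf4 (-0.67 ± 0.09), at Aurkb (-0.67 ± 0.07), at Slc16a3 (-0.54 ± 0.07) and at Prdm1 (4135 ± 275 to 3108 ± 161, -0.41 ± 0.05). Over promoter regions alone Cd40lg (0.83) did not pass. Ifng (0.02 ± 0.04), Gzmb (-0.10 ± 0.05), Pdcd1 (-0.05 ± 0.05), Tox (-0.05 ± 0.05) and Zc3h12a (0.04 ± 0.05) did not pass the test, though Zc3h12a (-0.40) and Ifng (-0.30) passed as falls over promoter regions alone.

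Memory and stemness genes rose at 11 of 20, with Tcf7, Ccr7 (0.42) and Lef1 (0.34), and fell at 1, Myb (-0.36 ± 0.08, not past the test over promoter regions at -0.06; median 0.16, camera adjusted p 0.000241). Regnase-1 mRNA targets rose at 6 of 14, with Ptgs2 (1.21), Il6 (1.16), Il4 (1.09) and Icos, and fell at 1, Tnfrsf4 (camera adjusted p 0.00174; 7 rises adjusted over the list alone). AP-1 and IRF factors rose at 7 and fell at 4 of 20, Batf, Maf and Nfatc1 (0.50) against Jund (-0.38 ± 0.06) and Junb (-0.30; camera adjusted p 0.00701, turning downward at 0.888 over promoter regions alone). Effector genes fell at 10 of 20 and rose at 1, Zeb2 (0.26 ± 0.06, not past the test over promoter regions at 0.06), with Il2rb (-0.51), Prdm1 and Tbx21 (-0.39) among the falls (camera adjusted p 0.0361, lost at 0.0721 with total counts). Cell cycle genes fell at 13 and rose at none of 22 (camera adjusted p 0.0111; 14 falls adjusted over the list alone). Glycolysis genes fell at 12 and rose at 1 of 19, Hk2 (0.21 ± 0.05, turning to -0.08 over promoter regions; camera adjusted p 0.0111; 13 falls adjusted over the list alone). Melanoma markers rose at 1 of 8, Kit (camera adjusted p 0.0238), with Mlana at 0.20 ± 0.09 and Pmel at -0.10 ± 0.08, neither past the test. None of the 7 calls held with an estimated correlation: adjusted p = 0.144 for the memory, Regnase-1 target, AP-1 and melanoma lists, 0.584 for cell cycle and glycolysis and 0.621 for effector genes. From regions beyond 1 kb of a TSS the cell cycle, glycolysis and melanoma lists were not called (0.466, 0.648 and 0.585), and over promoter regions alone the cell cycle and effector lists were not (0.0754 and 0.0921). Adjusted over the list alone, the memory, AP-1, effector and melanoma counts were the same. Markers of other cell types that were not called rose and fell at 0 and 5 of 12 for NK cells, 5 and 1 of 10 for stroma (camera adjusted p 0.0552), 4 and 2 of 12 for CD4 and regulatory T cells, 2 and 2 of 13 for myeloid cells and 3 and 1 of 11 for B cells, called upward from promoter regions (0.01996). Upward there is relative to all genes, whose median over promoter regions was -0.20.

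At region level 17218 regions rose and 15631 fell, 9598 and 4320 at least 2-fold. The Erich3 region named above rose from 8.26 ± 6.34 to 399 ± 54.8 (5.77 ± 0.28, adjusted p 1.74e-24), followed under the naming rule by regions assigned to Pdss1 (5.61), Gpr4 (5.14), Rpl37rt (5.10), Fam43a (5.08) and Nr2c1 (chromosome 10, 93555657 to 93556610, 5.06). Falls under the naming rule were led by Adgrd1 (-2.73 ± 0.22), Ccl24 (-2.68), Fry (-2.65, the region named above), Samd4b (-2.64), Synrg (-2.63) and a region upstream of Il7r, the receptor for a T cell survival cytokine (chromosome 15, 9499122 to 9499621, 74.7 ± 17.6 to 12.6 ± 7.15, -2.59 ± 0.26). The Tcf7 upstream region rose by 2.67 ± 0.20 and a Tox intron region (chromosome 4, 6895921 to 6896420) by 3.76 ± 0.39. That Tox region started from a low signal, 3.14 ± 2.48 in WT against 48.1 ± 10.4 in dKO. Promoters had a median of -0.19 against 0.02 elsewhere and made up 5.65% of rises and 35.8% of falls (Fisher's exact test, odds ratios 0.283 and 3.75). At gene level 2636 genes rose and 6039 fell. Rises were 52.4% of called regions and 30.4% of called genes as deposited, 68.3% and 56.7% with equal promoter medians (gene median -0.11 as deposited, then 0.01), and 42.5%, 41.4%, 53.3% and 50.4% of genes with total counts, loess offsets, edgeR and DESeq2.

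dKO against Reg1_KO asks what loss of Batf changes in cells that lack Regnase-1 (4 libraries each). Accessibility fell at some exhaustion genes, among them Cd38 (1116 ± 48.3 to 638 ± 37.8, -0.81 ± 0.07), Havcr2 (1607 ± 152 to 929.9 ± 42.8, -0.79 ± 0.06, limma adjusted p 3.39e-13), the factor Tox2 (-0.59 ± 0.05) and Pdcd1 (4015 ± 181 to 3079 ± 193, -0.38 ± 0.05, adjusted p 3.59e-09). It also fell at Gzmk (-1.02 ± 0.09), Itga1 (2568 ± 139.8 to 1617 ± 45.5, -0.67 ± 0.06), Maf (-0.45 ± 0.04) and Ifng (-0.25 ± 0.04, 0.0033 over promoter regions). It rose at Id3 (1199 ± 64.3 to 2145 ± 123, 0.84 ± 0.05), Ccr7 (0.66 ± 0.06), Aurkb (0.71 ± 0.07), Nr4a1 (0.64 ± 0.05), also an exhaustion gene, Fosb (0.56 ± 0.05), Tcf7 (3308 ± 229 to 4841 ± 221, 0.55 ± 0.04, adjusted p 3.05e-13) and Batf (0.36 ± 0.05). Gzmb (-0.12 ± 0.05), Tox (-0.10 ± 0.05) and Zc3h12a (0.08 ± 0.05) did not pass, and over promoter regions alone neither did Maf (-0.24) and Itga1 (-0.34), while Tox passed as a rise (0.35). Zc3h12a passed as a fall with equal promoter medians (-0.13).

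Exhaustion genes fell at 9 and rose at 4 of 19, Nr4a1, Lag3 (0.33), Cd160 and Nr4a3 being the rises, with 10 falls adjusted over the list alone (median -0.11, camera adjusted p 0.00933, adjusted p = 0.505 with an estimated correlation). Tissue residency genes fell at 6 of 13, with Itga1, Itgae (-0.49) and Prdm1 (-0.46), and rose at 1, P2rx7 (0.20 ± 0.08, turning to -0.0034 with equal promoter medians), with the same counts adjusted over the list alone (camera adjusted p 0.00933, adjusted p = 0.316 with an estimated correlation). Neither list was called from promoter regions alone (0.216 and 0.209) or from regions beyond 1 kb (0.0786 and 0.0674). Without Reg1_KO 2, 4 lists were called. Memory and stemness genes, not called as a list, rose at 8 and fell at 5 of 20, the falls being Cxcr3 (-0.48), S1pr1 (-0.32 ± 0.04, turning to 0.26 over promoter regions), Il7r, Satb1 and Lef1. Mitochondrial genes rose at 17 and fell at 3 of 29 and cell cycle genes at 11 and 1 of 22. With equal promoter medians the counts were 7 and 6 and 8 and 7, and the cell cycle median turned from 0.19 to -0.01. Markers of other cell types, not called, rose and fell at 3 and 6 of 12 for NK cells (camera adjusted p 0.0656, called downward from promoter regions at 0.0235), 2 and 4 of 12 for CD4 and regulatory T cells (0.0797), 5 and 3 of 11 for B cells, 4 and 1 of 13 for myeloid cells, 1 and 2 of 8 for melanoma and 3 and 3 of 10 for stroma. Downward from promoter regions is relative to all genes, whose median there was 0.26.

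At region level 21032 regions rose and 18080 fell, 6625 and 8936 at least 2-fold. Rises under the naming rule were led by an intron region assigned to Stpg4 (chromosome 17, 87762254 to 87762753, 11.3 ± 2.63 to 147 ± 14.1, 3.60 ± 0.26), Hmga2-ps1 (3.08), Rnf130 (2.73), the kinase Sik1 (2.71), Smim23 (2.66) and Tead1 (2.59). Falls under that rule were led by Arl6ip1 (chromosome 7, 125279017 to 125279516, -3.23 ± 0.24), Myo10 (-3.21), Clcc1 (-3.20), Stbd1 (-3.16), Nr2c1 (-2.97) and Atp2b3 (-2.96). This Nr2c1 region (chromosome 10, 93587902 to 93588401) is not the one that rose in dKO against WT. The Pdcd1 intron region that was lower in Batf_KO fell from 804 ± 79.8 to 366 ± 112 (-1.17 ± 0.11), and a region upstream of Tox (chromosome 4, 7099616 to 7100115) fell too (-1.38 ± 0.20). Promoters had a median of 0.25 against -0.01 elsewhere and made up 35.4% of rises and 5.02% of falls (Fisher's exact test, odds ratios 4.08 and 0.246). At gene level 7021 genes rose and 3189 fell. Rises were 53.8% of called regions and 68.8% of called genes as deposited, 30.2% and 35.7% with equal promoter medians (gene median 0.12 as deposited, then -0.08) and 57.8%, 49.1% and 52.7% of genes with loess offsets, edgeR and DESeq2.

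dKO against Batf_KO asks what loss of Regnase-1 changes in cells that lack Batf (4 libraries against 2). Accessibility rose at Kit (543 ± 66.3 to 1706 ± 54.5, 1.65 ± 0.08, limma adjusted p 1.38e-19), Il6 (1.37 ± 0.10), Cd40lg (1.33 ± 0.11), Icos (1279 ± 61.4 to 2723 ± 121, 1.09 ± 0.06), Itga1 (868 ± 39.5 to 1617 ± 45.5, 0.90 ± 0.07), Batf (0.62 ± 0.06) and Maf (0.57 ± 0.04). It fell at the cell cycle kinase Cdk2 (-0.90 ± 0.13), Rgs16 (-0.80 ± 0.10), Id3 (3367 ± 185 to 2145 ± 123, -0.65 ± 0.07) and the glycolytic enzyme Aldoa (-0.61 ± 0.09). Pdcd1 rose by 0.21 ± 0.06. Zc3h12a fell (-0.15 ± 0.06) but stood at 0.02 with total counts, 0.06 with loess offsets and 0.09 with equal promoter medians, and Gzmb fell (-0.18 ± 0.07) but stood at 0.06 with equal promoter medians. Zc3h12a did not pass without Batf_KO 1 (-0.16), Batf_KO 2 (-0.14), dKO 3 (-0.13) or dKO 4 (-0.13), nor Gzmb without Batf_KO 1 (-0.14) or dKO 2 (-0.15). Tcf7 (0.08 ± 0.05), Ifng (0.04 ± 0.05) and Tox (0.12 ± 0.06) did not pass, though over promoter regions alone Tcf7 (-0.38) and Tox (-0.56) passed as falls. Batf (0.23) and Cd40lg (0.56) did not pass over promoter regions alone, nor Rgs16 (-0.40) and Aldoa (-0.39) over regions beyond 1 kb of a TSS.

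Cell cycle genes fell at 17 and rose at none of 22, with Cdk2, Birc5 (-0.73) and Top2a (-0.65; median -0.40, camera adjusted p 0.00527). Glycolysis genes fell at 14 and rose at none of 19, with Aldoa, Slc16a3 (-0.60) and Eno1 (-0.57; camera adjusted p 0.0117, lost at 0.0714 with total counts). Regnase-1 mRNA targets rose at 5 (Il6, Icos, Il4 (0.80), Cxcl2 and Ctla4) and fell at 4 of 14 (Tnfrsf4 (-0.53), Nfkbid, Rel and Zc3h12a; camera adjusted p 0.0117). Melanoma markers rose at 2 of 8, Kit and Trpm1 (camera adjusted p 0.0117), and NK cell markers rose at 5 and fell at 2 of 12, Klra8 (0.78), Klra1 (0.71) and Klra7 (0.66) among the rises (camera adjusted p 0.0377, lost at 0.0583 with a replicate block). Adjusted over the list alone, glycolysis gave 1 rise and NK markers 3 falls, and the other 3 lists the same counts. None of the 5 calls held with an estimated correlation (adjusted p = 0.464 for cell cycle, 0.465 for glycolysis and 0.157 for the other 3) or from regions beyond 1 kb of a TSS (0.373, 0.661, 0.131, 0.373 and 0.715 in the order above). Other markers of cell types, not called, rose and fell at 1 and 2 of 11 for B cells and 3 and 4 of 13 for myeloid cells, both called upward from promoter regions (0.0200 and 0.049996), 3 and 4 of 12 for CD4 and regulatory T cells and 4 and 2 of 10 for stroma. Upward from promoter regions is relative to all genes, whose median there was -0.36. Total counts called the CD4 and regulatory T cell list upward (camera adjusted p 0.0395), and also the exhaustion (0.0347) and tissue residency lists (0.0240).

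At region level 14387 regions rose and 14236 fell, 8859 and 3540 at least 2-fold. Rises under the naming rule were led by regions assigned to Cep83os (chromosome 10, 94100682 to 94101181, 5.12 ± 0.34), Erich3 (5.06), Prss12 (5.02), Tmcc3 (4.87), Pdss1 (4.70) and Rpl37rt (4.67). Falls under that rule were led by Fry (383 ± 14.3 to 44 ± 3.09, -3.09 ± 0.23), Rap1gap (-2.94), Os9 (-2.73), Gng10 (-2.72), Tpmt (-2.71) and Rpl21 (-2.69). A region just past the end of Ifng (chromosome 10, 117883208 to 117883707) rose by 1.84 ± 0.26, an intron region of Batf (chromosome 12, 87030113 to 87030888) by 3.51 ± 0.43 and the Tcf7 upstream region by 1.98 ± 0.24. That Batf region started from a low signal, 3.46 ± 1.82 in Batf_KO against 48.1 ± 9.02 in dKO. Promoters had a median of -0.33 against 0.08 elsewhere and made up 4.21% of rises and 52.2% of falls (Fisher's exact test, odds ratios 0.210 and 8.70). At gene level 2188 genes rose and 7301 fell. Rises were 50.3% of called regions and 23.1% of called genes as deposited, 69.5% and 48.4% with total counts (gene median -0.18 as deposited, then -0.01), 77.1% and 61.9% with equal promoter medians (0.05) and 39.2%, 51.0% and 49.1% of genes with loess offsets, edgeR and DESeq2. Without Batf_KO 1, 7299 regions and 4708 genes fell.

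The interaction asks whether the change on losing Batf differs between cells with and without Regnase-1. At gene level it was negative at Maf (-0.51 ± 0.06, limma adjusted p 2.3e-08), whose signal was 4485 ± 88.1 in WT, 9487 ± 412 in Reg1_KO, 4688 ± 97.7 in Batf_KO and 6949.9 ± 52.2 in dKO, and at Lef1 (-0.38 ± 0.06), Ifng (-0.24 ± 0.06) and the signalling enzyme Plcg1 (-0.45 ± 0.07). The values for Ifng and Plcg1 turned to 0.25 and 0.17 over promoter regions. It was positive at Aurkb (0.80 ± 0.12, adjusted p 7.79e-06), Jund (0.50 ± 0.10) and the glycolytic enzyme Pgk1 (0.35 ± 0.07). Maf (-0.30) and Jund (0.16) did not pass over promoter regions alone, Pgk1 (0.13) over regions beyond 1 kb or Ifng (-0.20) without Batf_KO 1. Batf lay at the threshold (0.22 ± 0.08, adjusted p 0.05) and did not pass in most alternatives, among them edgeR (0.18) and the omission of Batf_KO 2 (0.10). It did not pass at Tcf7 (0.00 ± 0.07, adjusted p 0.982), Pdcd1 (-0.12 ± 0.07), Tox (0.07 ± 0.08), Gzmb (-0.19 ± 0.09) or Zc3h12a (-0.11 ± 0.07), so the changes of their summed signals on losing Batf were not shown to differ between the 2 settings. Individual regions, each with the lowest p of its gene, passed at Tox (3.34 ± 0.77), Gzmb (-1.55), Zc3h12a (-0.87) and Pdcd1 (0.62). That choice favours a call, since these genes have 59, 20, 22 and 23 regions and 5.77% of all tested regions were called. The Tox region had low signal, 10.6 in WT, 3.06 in Reg1_KO, 3.91 in Batf_KO and 16.6 in dKO.

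Memory and stemness genes were the 1 list called: 7 of 20 were lower and 1, Bcl6 (0.28 ± 0.09, not past the test with equal promoter medians at 0.19), higher than the sum of single losses (8 and 1 adjusted over the list alone), with Satb1 (-0.44), S1pr1 (-0.38) and Lef1 among the former (median -0.17, camera adjusted p 0.00193). The call was lost with an estimated correlation (adjusted p = 0.435) and over promoter regions (0.0669). Tissue residency genes were lower at 4 and higher at none of 13, including Itgae (-0.40) and Itga1 (-0.31). TCR signalling genes were lower at 4 and higher at none of 20, including Plcg1 and Lcp2 (-0.44), with 5 lower adjusted over that list alone. Neither list was called (camera adjusted p 0.0625 and 0.124), but both were with a replicate block (0.0253 and 0.0331). Without 1 library, 2 lists were called without WT 2, WT 3, Reg1_KO 2 or dKO 4, and 3 without Reg1_KO 1 or Batf_KO 2.

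At region level the interaction was positive at 2910 regions and negative at 4291. Positive values under part (a) of the naming rule were led by Slmap (2.79 ± 0.42), Ube2f (2.56), Stpg4 (2.48), Fut8 (2.34), the heat shock gene Hspa1a (2.24) and Rad51b (2.18). Negative ones included Sgms1 (-3.12 ± 0.36), Map3k4 (-3.05), a region upstream of Maf (chromosome 8, 118294837 to 118295336, -2.90 ± 0.32), Atp6v1e1 (-2.89) and Msn (-2.77). That Maf region had 22.5 ± 4.75 in WT, 184 ± 20.1 in Reg1_KO, 39.1 ± 1.62 in Batf_KO and 42.3 ± 9.49 in dKO. Promoters had a median of 0.12 against 0.02 elsewhere and made up 31.5% of positive and 5.43% of negative calls (Fisher's exact test, odds ratios 2.51 and 0.297). At gene level 1686 genes were positive and 1490 negative. Positive values were 40.4% of called regions and 53.1% of called genes as deposited, 53.3% and 69.1% with total counts, 23.6% and 28.1% with equal promoter medians and 42.3% of genes with edgeR. Positive regions numbered 1903, 1818 and 1199 without WT 2, WT 4 and Batf_KO 2, and negative regions 2655 and 2282 without Batf_KO 1 and 2. Positive genes numbered 394 without Batf_KO 2, and negative genes 923 and 816 without Batf_KO 1 and 2. Without the 3 libraries nearest to another group 2576 genes were positive.

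**Figure D5:**
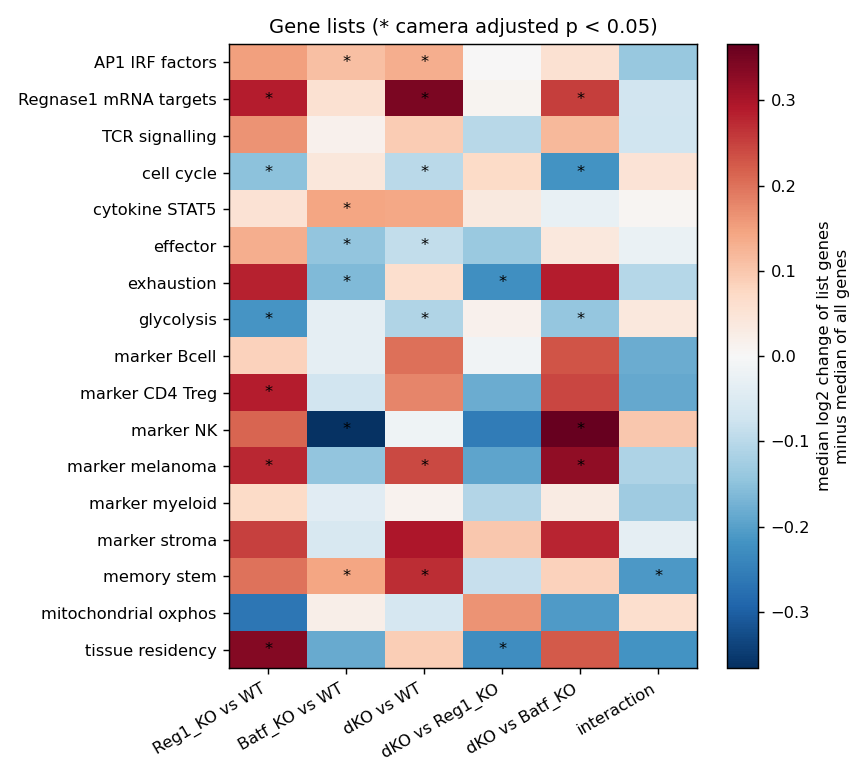
Colours give the median log2 change of the genes of each list minus the median of all genes (colour scale) for the 17 lists (rows) and 6 comparisons (columns), with a star where camera called the list. Regnase-1 mRNA targets and melanoma markers, among which Kit, are starred in all 3 comparisons that differ by Regnase-1, cell cycle and glycolysis in the same 3. None of these 12 calls held with an estimated correlation (adjusted p 0.144 to 0.584).

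Changes on losing Regnase-1 were compared between cells with Batf (Reg1_KO against WT) and without it (dKO against Batf_KO), which share no library. Across the 124698 regions the log2 changes had a Pearson correlation of 0.560 (Spearman 0.524) and the same sign at 69.5%; regions are not independent replicates. Regions that rose in Reg1_KO had a median of 0.98 with Batf and 0.54 without it. Of these, 9368 of 23413 (40.01%) were called higher without Batf too, against 2701 for independent lists, which take no account of promoter class. Regions that fell had -0.81 and -0.44, and 9929 of 22414 (44.3%) were called lower in both. The region upstream of Tcf7, for example, rose by 2.47 with Batf and 1.98 without it, and the summed signal of Icos by 1.11 and 1.09. For loss of Batf with and without Regnase-1 the Pearson correlation was 0.434, and 4276 of 7866 rising regions (54.4%) and 5039 of 7961 falling ones (63.3%) were called the same way in both. Without Batf_KO 1 or 2 the Regnase-1 correlation was 0.493 and 0.520.

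Regions changed by loss of Regnase-1 were also compared with those changed by further loss of Batf. Of the 23413 regions higher in Reg1_KO than in WT, 10440 (44.6%) were lower in dKO than in Reg1_KO, against 3395 for independent lists. Of the 22414 lower regions 12406 (55.3%) were higher in dKO, against 3780. Independent lists take no account of promoter class. Promoters made up 44.4% of these lower regions and 35.4% of those higher in dKO than in Reg1_KO, so 3780 is too low an expectation. Both comparisons use the Reg1_KO libraries, which alone makes opposite changes. Simulated libraries without any difference between genotypes, with as many top-ranked regions taken, gave 35.4% to 36.1% and 40.03% to 40.7%. Regions taken there owe their rank to spread alone, so these shares do not give the part due to sharing in the real data. Across regions the covariance of the 2 log2 changes was -0.277, against a mean of -0.0515 in the simulated libraries. With the Reg1_KO libraries divided into 2 pairs, 1 for each comparison, so that none was shared, the shares were 34.8% to 42.2% and 32.8% to 42.6%, which is 3.55 to 3.77 and 2.89 to 3.21 times those of independent lists. At an adjusted p of 0.01 they were 39.8% and 50.2%. Pdcd1 and Itga1 followed this order at gene level, at 4015 ± 181 in Reg1_KO and 3079 ± 193 in dKO and at 2568 ± 139.8 and 1617 ± 45.5. Icos and Kit also fell, from 3049 ± 181 to 2723 ± 121 (log2 change -0.16 ± 0.05, adjusted p 0.00836) and from 2026 ± 192 to 1706 ± 54.5 (-0.24 ± 0.07, adjusted p 0.00247).

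Of the 284 listed symbols 18 had no measured gene: Cd39, Il1rn, Cxcl1, Ndufb5, Sdhc, Atp5a1, Pkm2, Zfp683, Pax5, Lyz2, Emr1, C1qb, Tyr, Tyrp1, Sox10, Slc45a2, Tek and Dcn. Median, mean and camera direction differed in sign for 30 of the 102 list results and for 0 of the 27 called ones. In Reg1_KO against WT these were AP-1 and IRF factors, effector, B cell, myeloid and TCR genes. In Batf_KO against WT they were B cell, CD4 and regulatory T cell, melanoma, myeloid and stroma markers and Regnase-1 targets, and in dKO against WT myeloid, TCR and residency genes. In dKO against Reg1_KO they were B cell, CD4 and regulatory T cell, myeloid and stroma markers, Regnase-1 targets and TCR genes. In dKO against Batf_KO they were AP-1 and IRF factors, effector, exhaustion, B cell and myeloid genes, and in the interaction AP-1 and IRF factors, cytokine and STAT5, effector, myeloid and stroma genes.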

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

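Tests chosen only after the result was seen were the comparison of promoter shares at similar read numbers and the test for cells without Regnase-1 loss among dKO cells; scaling to equal promoter medians and the omission of 3 libraries were also chosen then.

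Regions within 1 kb of a TSS lay lower, relative to others, in libraries without Regnase-1. Weaker enrichment of strong signal is argued against as the whole cause in 10 strata of equal mean signal, made from the regions of highest signal. There promoters changed by -0.561 more than other regions on average in Reg1_KO against WT (95% interval over strata -0.624 to -0.489). In dKO against Batf_KO the value was -0.334 (-0.370 to -0.290). These intervals come from resampling strata and do not measure the spread between libraries. In Reg1_KO against WT, other regions had a median change of 0.159 in the stratum of lowest signal and -0.144 in that of highest. In dKO against Batf_KO these medians were 0.0555 and -0.227. Weaker enrichment beside other causes therefore stays open. Fewer reads are argued against too, since the lowest Batf_KO library, at a similar depth, exceeded the highest Reg1_KO library by 11.7 percentage points, against a range of 2.28 within Reg1_KO. An effect of genotype on promoters, or on regions elsewhere that take up reads, may explain the pattern and remains a hypothesis. GC content and differences in handling that go with genotype were not tested and stay open.

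Regions that rose in Reg1_KO rose less when Batf was absent too. Selection of regions by the libraries that give their change is argued against: with regions called on 2 and 2 libraries and measured on the other 2 and 2, the median change was 0.92 to 1.10 over 9 splits, against 0.56 to 0.66 without Batf, and the smallest difference was 0.330. In all 9 splits WT 1 and Reg1_KO 1 served for the call, and the reverse splits were not run. WT 1, which deviated towards Reg1_KO (0.129), was thus never among the measured libraries, which may raise the measured change. A share of dKO cells without Regnase-1 loss is argued against as the whole cause, since 1 share would keep the same part of every rise. Regions were ranked by the interaction in 7 libraries and measured in the other 7, over 432 splits. Of 10 groups of regions so ranked the lowest kept 0.0597 to 0.156 of its rise without Batf and the highest 0.815 to 1.077, and the smallest difference was 0.705. In simulated libraries with 1 share everywhere the difference was -0.0666 to 0.0438. A stricter form tried first, that some group rose more without Batf than with it, did not decide, since the interaction of the highest group was -0.13 to 0.09. Such a share beside other causes stays open, and so does a requirement for Batf that differs between regions, which was not tested.

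WT 1, Reg1_KO 4 and dKO 4 lay nearer to another genotype than the other libraries of their groups. Cells or reads of another group in these libraries stay open, and no value decides: 3 of 3 deviated towards another group at both its higher and its lower regions, by up to 0.200, against 2 of the 9 other libraries, by up to 0.0749, but the 3 were chosen for lying near another group. No deviation pointed to 1 group alone: WT 1 deviated towards dKO (0.200), Batf_KO (0.196) and Reg1_KO (0.129), Reg1_KO 4 towards dKO (0.146), WT (0.145) and Batf_KO (0.0998), and dKO 4 towards WT (0.196), Batf_KO (0.144) and, below the cut, Reg1_KO (0.0259). A difference in promoter enrichment alone is argued against, since with promoters left out the largest deviation of each library was at least 0.150 (Reg1_KO 4, towards WT, with 0.144 towards dKO). Without the 3 libraries 2576 genes had a positive interaction, against 1686. No biological explanation was tested.

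Chance is argued against as the source of the counts in the comparisons of 4 with 4 libraries. It is not excluded, since 1 of 35 is the smallest share of splits that this test can give. In fits of the 8 libraries alone, 1 of 35 splits, the real one, called as many, with 47340 regions in Reg1_KO against WT, 34670 in dKO against WT and 37740 in dKO against Reg1_KO, and the highest other split called 0 each time. For genes the real splits called 12234, 8991 and 9968, and the highest others 0, 1234 and 0. The split with 1234 genes put WT 1 with dKO 1, 2 and 3, so that WT 1 and dKO 4 changed places, which points to a structure of the samples.

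A library far from the other 3 of its group was sought by the gap to the nearest library over the group's range, where 0.829 is exceeded by chance in about 1 of 20 groups. Among 21 sets of library measures 2 exceeded it: the promoter share of Reg1_KO 3 (0.887) and the share of chromosome X in dKO 1 (0.850). Among 309 sets of named genes 26 did, 17 of them in dKO, where dKO 4 was the library apart 12 times. In dKO they were Slc16a3 0.973, Fyn 0.921, Cd5 0.890, Sparc 0.889, Slc2a3 0.884, Ccl3 0.876, Il6 0.874, Lef1 0.872 and S1pr1 0.868. Smaller gaps there were Plcg1 0.859, Cxcr3 0.859, Cd79b 0.843, Pim1 0.840, Lcp2 0.834, Cdk2 0.834, Ccnd3 0.832 and Prdm1 0.829. In WT they were Tfam 0.952, Ccnd2 0.938, Tcf7 0.888, Klri2 0.870, Ndufa4 0.852 and Zeb2 0.830, and in Reg1_KO Pgk1 0.947, Lcp2 0.867 and Tyrobp 0.857.

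Among 264 sets of named regions 20 exceeded it. In WT they were assigned to Pdss1 0.970, Batf 0.961, Nr2c1 0.914, Gpr4 0.885, Tcf7 0.879, Batf 0.873, Slmap 0.869, Gzmb 0.857 and Adgrd1 0.829. In Reg1_KO they were assigned to Arl6ip1 0.994, Sar1a 0.932, Rbl2 0.910, Zc3h12a 0.884 and Ifng 0.861, and in dKO to Tox 0.972, Synrg 0.890, Gzmb 0.863, Fry 0.860, Khdc1b 0.842 and Batf 0.839. A gene given more than once has more than 1 such region.

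Changes on losing Batf differed with Regnase-1 status, by the interaction, at 2910 regions upward and 4291 downward and at 1686 and 1490 genes. Without Batf_KO 2 these were 1199, 2282, 394 and 816, without Batf_KO 1 the downward ones were 2655 and 923, and without WT 2 and WT 4 the upward regions were 1903 and 1818. Of the named genes 27 passed. Positive values were Ncr1 1.74, Sparc 0.84, Aurkb 0.80, Jund 0.50, Cebpb 0.47, Ccl3 0.45, Ogdh 0.43, Pgk1 0.35, Pim1 0.33, Bcl6 0.28, Batf 0.22 and Ctla4 0.21. Negative values were Itgam -0.54, Klre1 -0.53, Ccnd2 -0.51, Maf -0.51, Ebf1 -0.45, Plcg1 -0.45, Lef1 -0.38, Epas1 -0.33, Il2ra -0.29, Xcl1 -0.29, Nfkbiz -0.27, Trpm1 -0.25, Ifng -0.24, Entpd1 -0.23 and Ccnd3 -0.19. The values of Ifng, Entpd1 and Plcg1 turned in sign over promoter regions alone.

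Of the named regions 17 passed the test of the interaction. Positive values were those assigned to Tox 3.34 (a region of low signal), Slmap 2.79, Ube2f 2.56, Stpg4 2.48, Fut8 2.34, Hspa1a 2.24, Rad51b 2.18, Batf 1.11 and Pdcd1 0.62. Negative values were those assigned to Sgms1 -3.12, Map3k4 -3.05, Maf -2.90, Atp6v1e1 -2.89, Msn -2.77, Gzmb -1.55, Ifng -1.42 and Zc3h12a -0.87. Memory and stemness genes passed as a list (camera adjusted p 0.00193, with 0.0669 over promoter regions and 0.435 with an estimated correlation as the far end of the alternatives).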

How the results depend on the processing

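Alternatives chosen after seeing the data were equal promoter medians, TMM scaling, edgeR, other pseudocounts, sums within 100 kb or beyond 1 kb of a TSS, and leaving out values of 1 read or the 3 libraries nearest to another group. A value past the threshold was counted as kept if it stayed past it in the same direction, and a value not past it if it stayed so, whatever its sign. Named regions were kept in 1537 of 1543 recomputed values, and 0 turned in direction. They had been chosen for large changes or the lowest p, which favours this result. For named genes 3256 of 3550 values were kept, 168 were no longer past the threshold, 71 newly passed it and 55 turned, 41 of them past it before and 14 newly past it with the other sign. For gene lists 438 of 510 were kept, 54 were no longer past it, 16 newly passed and 2 that had been called turned. Among kept values that were not past the threshold the sign turned in 37 of 299 for genes and 40 of 359 for lists. With 1 library left out the same held for 1551 of 1568 region values, 2853 of 2982 gene values and 1407 of 1428 list values, and 0 that were past it turned. Among kept values not past it the sign turned in 12 of 315 for genes and 23 of 1035 for lists. At region level edgeR shared 84.2% to 99.7% of the calls of limma and DESeq2 80.4% to 98.02%. Equal promoter medians kept 48.0% (lower regions in dKO against Batf_KO) to 100% of them, with 51.8% of lower regions in Reg1_KO against WT. Fewer simulated changes were recovered for the interaction: of 2-fold changes 26.9% of regions, against 55.2% for Reg1_KO against WT. Depth and number of libraries were not varied in that simulation. A search for sequence motifs and a test of GC content were not run, because they need the mm9 sequence. Edits by the sgRNAs cannot be seen in these values.

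Counts moved by more than 1.5 times in the following cases, and the cause was not tested except where fewer genes or regions were tested (13735 genes have a promoter region, 17628 a region beyond 1 kb, and 62349 regions lie at or above the median signal). Scaling to equal promoter medians gave 40816 higher and 11600 lower regions, 7981 higher and 4541 lower genes in Reg1_KO against WT, 4981 higher regions, 1079 higher and 1963 lower genes in Batf_KO against WT, 10086 lower regions, 4308 higher and 3289 lower genes in dKO against WT. It also gave 11799 higher and 27306 lower regions, 3512 higher and 6332 lower genes in dKO against Reg1_KO, 23029 higher and 6831 lower regions, 4745 higher and 2919 lower genes in dKO against Batf_KO, 1847 higher regions, 1068 higher and 2732 lower genes in the interaction. Summing promoter regions alone gave 977 higher genes in Reg1_KO against WT, 1504 higher and 157 lower genes in Batf_KO against WT, 743 higher genes in dKO against WT. It also gave 712 lower genes in dKO against Reg1_KO, 484 higher genes in dKO against Batf_KO, 1077 higher and 236 lower genes in the interaction. Summing regions beyond 1 kb of a TSS alone gave 3703 lower genes in Reg1_KO against WT, 1795 higher and 1935 lower genes in Batf_KO against WT, 2763 lower genes in dKO against WT. It also gave 3407 higher genes in dKO against Reg1_KO, 3306 higher and 2217 lower genes in dKO against Batf_KO, 946 higher genes in the interaction. edgeR gave 6863 higher and 5637 lower genes in Reg1_KO against WT, 1678 higher genes in Batf_KO against WT, 4292 higher and 3765 lower genes in dKO against WT. It also gave 4913 lower genes in dKO against Reg1_KO, 4065 higher and 3906 lower genes in dKO against Batf_KO. DESeq2 gave 6341 higher genes in Reg1_KO against WT, 1649 higher and 1708 lower genes in Batf_KO against WT. It also gave 4055 higher and 3997 lower genes in dKO against WT, 3947 higher and 4086 lower genes in dKO against Batf_KO. Total-count scaling gave 5187 higher regions, 1185 higher and 1948 lower genes in Batf_KO against WT, 8880 lower regions, 3920 higher and 4185 lower genes in dKO against Batf_KO, 4426 higher regions, 2810 higher genes in the interaction. Loess offsets gave 1813 higher genes in Batf_KO against WT, 4724 lower genes in dKO against Batf_KO. Testing only regions at or above the median signal gave 10798 higher regions in dKO against WT. Leaving out the 3 libraries nearest to another group gave 2576 higher genes in the interaction.

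Gene lists called by camera with an estimated correlation numbered 0 in Reg1_KO, 2 in Batf_KO and 0 in dKO against WT, 0 in dKO against Reg1_KO, 0 in dKO against Batf_KO and 0 in the interaction (3, 3, 5, 2, 3 and 1 at an unadjusted p under 0.05). From regions beyond 1 kb of a TSS they numbered 0 in Reg1_KO and 4 in dKO against WT, 0 in dKO against Reg1_KO and 0 in dKO against Batf_KO (3, 5, 3 and 2 unadjusted), and from promoter regions 0 in the interaction (3 unadjusted). The share of regions higher in Reg1_KO and lower in dKO was 39.8% at an adjusted p of 0.01 and 38.5% as the mean over 6 splits with 2 Reg1_KO libraries in each comparison. The opposite share was 50.2% and 37.8%. Among regions called in Reg1_KO against WT the correlation of the Regnase-1 changes with and without Batf was 0.740. This pools rises and falls without the regions between them. Within regions called higher it was 0.534 and within those called lower 0.342, against 0.560 over all tested regions.

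With each library left out in turn, counts ran as follows, and where 1 Batf_KO library was left it was assumed to vary like the other groups. In Reg1_KO against WT they were 20762 to 23808 higher and 19675 to 22769 lower regions, 3484 to 3894 higher and 8032 to 8590 lower genes and 6 to 7 lists. In Batf_KO against WT they were 3270 to 8273 higher and 5257 to 8316 lower regions, 842 to 3002 higher and 652 to 1190 lower genes and 5 to 6 lists. In dKO against WT they were 14919 to 17419 higher and 12040 to 15928 lower regions, 2338 to 2693 higher and 4903 to 6585 lower genes and 6 to 8 lists. In dKO against Reg1_KO they were 18144 to 21251 higher and 15615 to 18416 lower regions, 6447 to 7160 higher and 2845 to 3313 lower genes and 2 to 4 lists. In dKO against Batf_KO they were 9875 to 14649 higher and 7299 to 14557 lower regions, 1615 to 2235 higher and 4708 to 7481 lower genes and 4 to 5 lists. In the interaction they were 1199 to 3627 higher and 2282 to 4638 lower regions, 394 to 2324 higher and 816 to 1763 lower genes and 1 to 3 lists. The share of regions higher in Reg1_KO and lower in dKO was 40.7% to 46.3%, the opposite share 48.5% to 59.1%, and the correlation of the Regnase-1 changes with and without Batf 0.493 to 0.560.

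Summed over promoter regions alone, log2 changes of named genes turned in sign as follows. They were Batf -0.16, Tcf7 -0.31, Ifng -0.30, Gzmb -0.63, Tox -0.74, Ikzf2 -0.0482, Klrb1c 1.11 and Plcg1 -0.58 in Reg1_KO against WT, and Tox 0.17 in Batf_KO against WT. Values were Zc3h12a -0.40, Ifng -0.30, Hk2 -0.0781 and Tfam -0.0168 in dKO against WT, and Ifng 0.00331, Tox 0.35, Tnfrsf4 0.15, Hif1a 0.42, Trpm1 0.59, Kdr 0.29, S1pr1 0.26, Il6 0.18, Fyn 0.15 and P2rx7 -0.25 in dKO against Reg1_KO. Values were Tcf7 -0.38, Tox -0.56, Itgam 0.32 and S1pr1 -0.0928 in dKO against Batf_KO, and Ifng 0.25, Entpd1 0.0802 and Plcg1 0.17 in the interaction. Over regions beyond 1 kb of a TSS Zc3h12a turned to 0.18 in Reg1_KO against WT, Nfkbid turned to 0.23 in Reg1_KO against WT and Pgk1 turned to -0.0391 in dKO against Reg1_KO. Zc3h12a in Reg1_KO against WT turned to 0.18 with loess offsets, 0.29 with equal promoter medians, 0.19 with edgeR and 0.16 with DESeq2. Zbtb7b in Reg1_KO against WT turned to 0.0125 with equal promoter medians. Klrb1c in Reg1_KO against WT turned to 0.13 with equal promoter medians, 0.038 with edgeR and 0.00289 with DESeq2. Zc3h12a in dKO against Reg1_KO turned to -0.13 with equal promoter medians. P2rx7 in dKO against Reg1_KO turned to -0.00344 with equal promoter medians. Zc3h12a in dKO against Batf_KO turned to 0.0229 with total counts, 0.0568 with loess offsets, 0.0859 with equal promoter medians, 0.0422 with edgeR and 0.032 with DESeq2. Gzmb in dKO against Batf_KO turned to 0.0573 with equal promoter medians, 0.0128 with edgeR and 0.0024 with DESeq2. Klrb1c in dKO against Batf_KO turned to 0.00682 with total counts, 0.0699 with equal promoter medians, 0.0245 with edgeR and 0.014 with DESeq2. Only promoter regions turned the direction of the cytokine and STAT5 list in Batf_KO against WT (camera adjusted p 0.703) and of the AP-1 and IRF list in dKO against WT (0.888). The cause was not tested.

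Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.0231 to 0.0294, against -0.0899 to 0.0443 for other numbers, and 3 libraries correlated best with their own number. With a replicate block the interaction called 2318 regions higher and 3692 lower, 1397 genes higher and 1219 lower, and 3 lists. It called 23552 regions higher and 22543 lower in Reg1_KO against WT, and 6094 and 6690 in Batf_KO against WT. Lists called under the block numbered 6 in Reg1_KO, 7 in Batf_KO and 7 in dKO against WT, 2 in dKO against Reg1_KO and 4 in dKO against Batf_KO (6, 6, 7, 2 and 5 without it). Other counts of regions and genes under the block were within 1.5 times.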

Other observations

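The genes named here were chosen after their values were seen, while the test of gathering was written before its result. Called regions gathered at some genes. Of 3660 genes with at least 10 tested regions, 132 had at least 60% of them higher in Reg1_KO against WT, against at most 12 (mean 4.86) in 100 draws that placed as many calls at random among regions of like signal and promoter class, which argues against gathering by chance. Among them were Clnk, an adaptor of immunoreceptor signalling (11 of 11 regions, log2 change of the sum 2.44 ± 0.13), Prickle1, a planar polarity gene (38 of 42, 1.47 ± 0.06), Il6 (12 of 14), Itga1 (17 of 20) and Kit (21 of 25). In the other direction there were 64 such genes, against at most 6 in the draws, among them Ass1, which makes argininosuccinate (14 of 16, -1.22 ± 0.06).

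In Batf_KO against WT, where fewer regions were called, 2 such genes were higher and 5 lower, against 0 in the draws, with Id3 (9 of 14 regions) and the germ cell gene relative Gtsf1l (11 of 17, -1.08 ± 0.08). In dKO against WT there were 68 and 12, with Erich3 (23 of 24, 3.01 ± 0.09), the B cell receptor gene Tnfrsf13b (13 of 16, 1.83 ± 0.08) and the transcription factor Cebpd (9 of 11, 1.39 ± 0.10). In dKO against Reg1_KO there were 39 and 34. The AP-1 gene Fosb (12 of 17 regions) was among those higher, and the calcium channel gene Itpr1 (22 of 29, -0.71 ± 0.05) and the receptor Klrg1 of terminal effector cells (13 of 18, -0.66 ± 0.06) were among those lower. In dKO against Batf_KO there were 34 and 4.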
